A study of Mus musculus with 28 samples.

How the data were processed

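Gene expression was measured in splenic B cells of male C57BL/6 mice on 28 single-colour Affymetrix Mouse Gene 1.0 ST arrays, 1 per labelled time between 0.15 and 15 h after subcutaneous interferon alpha. Per the labels' protocols, CD19+ IgM+ cells were sorted by flow cytometry into TriZol, and RNA was amplified with a whole-transcript expression kit, labelled with biotin and hybridised. The protocol text comes in 2 wordings, called A and B here, with 14 arrays each. Wording A covers 1 of 3 arrays of 0.15-0.75 h, 2 of 3 of 1-1.5 h, all of 2-2.75 h and 3-4 h and 3 of 5 of 11-15 h, and B covers the rest. Wording was treated as a possible batch.

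The deposited table holds an intensity per probe set on a linear scale, summarised and normalised by the authors with Affymetrix Power Tools and RMA, per the submitters' processing notes. No version or genome build is given in the sources used here, so no coordinates are printed. The deposited intensities ran from 5.60 to 19417 over 24922 probe sets, with array medians between 93.9 and 114.4 and upper quartiles between 227 and 329. Medians were thus close to each other while the upper ends were not made equal. No pair of columns was identical, and every column was matched to its sample. For arrays, the number of arrays limits the precision.

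From these values log2 was taken with no pseudocount, since all were above 0, and no further scaling was applied in the chosen fits. Genes were named from GEO's platform annotation supplied for the table. Of the probe sets, 21425 carried 1 gene symbol, 1399 carried several and 2098 were not listed there. Probe sets with several symbols or none were left out of the tests by gene. A gene with several probe sets (921 genes) was given by the probe set with the highest mean over all arrays, which left 19752 genes. Symbols are those of the annotation, and 0 were updated through the Entrez identifier.

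Windows, tests, gene lists and the rule for named genes were fixed before the data were examined. The 28 arrays were grouped by labelled hour alone into 7 windows, and limma (version 3.58.1, in R 4.3.3) fitted window means with lmFit and eBayes on all 28 arrays, which share 1 estimate of the spread. The 6 later windows were each compared with 0.15-0.75 h, since no untreated array was available for comparison, and 11-15 h was also compared with 2-2.75 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Time dependence was tested with limma's moderated F test of a natural spline with 4 degrees of freedom in the square root of the hour. Kinetics were read from a natural spline with 5 degrees of freedom for genes called as time dependent and at least 2-fold higher in a called window between 1-1.5 h and 4.5-6.5 h. The hour of the fitted maximum and the hour at which 50 percent of the rise from the first array was reached (half-rise) were taken on a grid of 0.05 h, with 95 percent intervals from 1000 draws of the coefficients.

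The 30 lists with 567 genes, of which 500 were measured, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a contrast. They covered antiviral effectors, interferon pathway transcription factors, interferon receptor and kinases, negative feedback, nucleic acid sensors, ubiquitin-like and PARP genes, guanylate-binding and immunity-related GTPases, MHC class I and class II presentation, chemokines and cytokines, B cell activation, B cell identity, marginal zone B cells, plasma cells, lymphocyte trafficking, immediate early genes, heat shock, glucocorticoid targets, circadian clock, cell cycle, cell death, sterol synthesis, ribosomal proteins, oxidative phosphorylation and NF-kB targets. Markers of T cells, NK cells, myeloid cells, dendritic cells and erythroid cells were included as other cells a sort could hold. Camera with an estimated correlation and fry, which asks only whether a list's genes move on balance one way, were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone.

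Named genes followed a fixed rule. Per window contrast these were the 14 called genes with the largest positive and the 8 with the largest negative log2 difference, from which the text takes a selection, and the 4 members of each list with the largest absolute difference. Irf7, Irf1, Socs1, Usp18, Ifit1, Mx1, Cxcl10 and Cd69 were followed in every contrast. Stat1, Isg15, H2-K1 and Cd19 were on that list too but had no probe set with a single symbol. For kinetics the 10 earliest and 10 latest half-rises were named, and for time dependence the 10 smallest p. Genes outside the rule are said to be so.

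The procedures were tested on simulated data on 19752 genes with 100 genes changed 2-fold and 100 changed 4-fold. At 2-fold, 84 percent were recovered for 1-1.5 h, 90 percent for 2-2.75 h, 83 percent for 3-4 h, 90 percent for 4.5-6.5 h, 89 percent for 7-10 h, 88 percent for 11-15 h, 91 percent for 11-15 h against 2-2.75 h and 86 percent for time dependence. At 4-fold 99 or 100 percent were recovered, and 7 to 15 unchanged genes were called per test. Simulated maxima at 1.5 and 3 h were fitted at 1.6 and 3.2 h. A list with changed members was called by all 3 list tests and 0 of 29 unchanged lists were called. The simulated noise was independent between genes and held no compressed arrays and no array far from the rest. The changed genes were drawn at random from all genes. In the data Cxcl10, 3.57 higher on the log2 scale in 1-1.5 h, did not pass with all arrays. These runs therefore do not show what share of interferon-induced genes is recovered. Nor do they show how the tests behave with correlated genes, the case in which the preset correlation matters.

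Alternatives were a wording term, leaving out the 6 arrays whose running number does not follow the hours, quantile normalisation, median centring, a filter on dim probe sets, all probe sets, a variance trend with robust hyperparameters, array weights, each array left out in turn, only the arrays of the windows compared, a slope of hour inside windows, a 2-fold minimum, another reference window, other splines and time scales, and the other list tests. Fits without 5 arrays with a compressed range, with the 0.15 h array alone as the reference, and within 1 wording where both windows held at least 2 of its arrays, and the singling out of the 2 h array were added after the data had been seen. The running numbers 7 and 13 do not occur among the samples and were not analysed here.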

Results

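Splenic B cells, the antibody-forming lymphocytes of the spleen, were profiled on microarrays along a course of 28 labelled times from 0.15 to 15 h after mice had received 10000 U of interferon alpha under the skin. Interferon alpha is a type I interferon, a cytokine that switches on antiviral genes through the Ifnar1 and Ifnar2 receptor chains and the Janus kinases. The labels give 1 array per time, no untreated array and no repeat of any time, and do not say whether an array holds 1 mouse or a pool. Neighbouring times were therefore joined into windows of 0.15-0.75 h (n = 3), 1-1.5 h (n = 3), 2-2.75 h (n = 4), 3-4 h (n = 4), 4.5-6.5 h (n = 5), 7-10 h (n = 4) and 11-15 h (n = 5). A window's SD spans neighbouring hours as well as arrays, and p-values measure only the spread between these arrays, which may be partly technical. Median intensity per array lay between 93.9 and 114.4, and the upper quartile between 227 and 329.

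Interferon-induced genes were near their lowest level at 0.15 h and close to their highest about 1 to 2 h later. Ifit1, whose product binds viral RNA, had a log2 intensity of 8.65 at 0.15 h, 10.91 at 0.5 h, 11.96 at 0.75 h and 12.42 at 1.25 h, and then 10.16 at 5 h and 10.06 at 15 h. The chemokine gene Cxcl10 was at 6.74 at 0.15 h, 12.35 at 1 h and 7.84 at 6 h. Irf7, a transcription factor of the interferon response, and Ifitm3, which blocks virus entry, stayed higher for longer. Irf7 was at 8.98 at 0.15 h, 12.12 at 2.25 h and 11.18 at 15 h, and Ifitm3 at 7.16, 12.55 and 10.92 at the same hours. Irf1, a transcription factor of the first wave, had its highest value, 11.77, already at 0.75 h. These are values of single arrays with no replicate.

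The array labelled 2 h stood apart from this course. Ifit1 was at 6.43 in it, between 12.27 at 1.5 h and 12.15 at 2.25 h, Irf7 was at 7.00 and Ifitm3 at 6.00. The median of the 27 measured antiviral effectors was 7.65 at 2 h, against 11.43 at 1.5 h and 11.57 at 2.25 h. A compressed range of values was seen in 5 arrays, those of 2, 2.5, 3.75, 4 and 4.5 h, which correlated at 0.952 to 0.984 with the median profile, while the other 23 correlated at 0.988 or more. In these arrays genes of the dimmest quartile lay 0.35 higher and genes of the brightest quartile 0.42 lower on the log2 scale than in the others, and B cell identity genes, which are bright, lay 0.47 lower (median -0.47). Every array was left out in turn as planned, and the values without the 2 h array, or without all 5 compressed arrays, stand beside the results below after being singled out once the data had been seen.

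**Figure D1:**
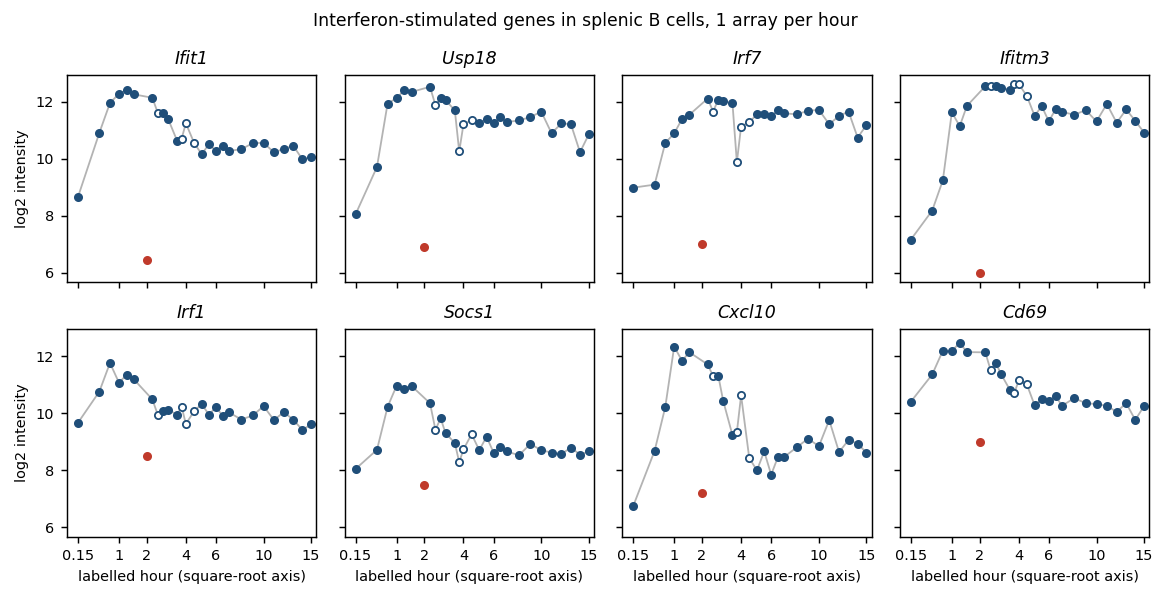
Log2 intensity (y axis) of interferon-induced genes against the labelled hour (x axis, square-root scale), with 1 point per array, open points for compressed arrays, a red point for the 2 h array and a grey line that passes over it. The plots show Ifit1 at 8.65 at 0.15 h and 12.42 at 1.25 h, with the 2 h array at 6.43.

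The test of time dependence asked which genes followed a smooth course over the 15 h. Bbs9, a part of the BBSome of the primary cilium, had the smallest p (F = 32.7, adjusted p = 3.47e-06) and ranged from 9.05 at 1.25 h down to 7.85 at 3.75 h. Pgap1, which remodels GPI anchors, ranged from 10.89 at 0.15 h to 9.10 at 4.5 h, and Cast, the calpain inhibitor, from 9.16 at 0.15 h to 8.25 at 4.5 h. Lbh ranged from 8.05 at 2.5 h to 10.08 at 10 h. Tas2r137, Ssbp3, Gdap2, Mical1, Ttll1 and Ghdc made up the 10. Of 19752 genes, 2036 passed and 5089 had an unadjusted p under 0.05. The lowest value lay in a compressed array for 9 of these 10 genes, and leaving out the 6 arrays out of the order of hours gave 539 genes.

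Induced genes reached their fitted maximum at a median of 3.2 h (quartiles 2.75 and 3.5 h) and their half-rise at a median of 1.25 h (0.70 h with a spline of 4 degrees of freedom) in the 59 genes that met the rule. Among these 59, the earliest half-rises were those of BC023105 and of P2ry13, a nucleotide receptor, at 0.5 h. They were followed by Car13, Ifi207, Il15 and Sgcb at 0.6 h and by Ddx60, Eya1, Hmgn3, Ifih1 and Ubxn2b at 0.65 h. The latest were those of Ppp1r14b at 2.65 h and of Alpl, Mif, Nolc1 and Snord42b at 2.3 h. Ergic1 and Pus7 at 2.25 h, Bcap29 and Nop16 at 2.2 h, and C1qbp, Dimt1 and Fabp7 at 2.15 h followed. The highest array was the compressed one of 3.75 or 4 h for Ppp1r14b, Nolc1, Snord42b, Ergic1, Bcap29, Nop16, Dimt1 and Fabp7. It was an uncompressed one for Alpl, Mif and C1qbp (3.5 h) and for Pus7 (2.75 h). Compression may thus have shaped part of these late half-rises. By window mean, 13 genes were highest in 1-1.5 h, 4 in 2-2.75 h and 42 in 3-4 h, and 12 never came back below the half-rise level by 15 h. When the 2 h array was left out, 206 genes met the rule, including all 59, with a median maximum at 2.175 h and a median half-rise at 0.6 h. Of these 206, 58 were highest in 1-1.5 h, 126 in 2-2.75 h and 22 in 3-4 h. In that set Socs1, a feedback inhibitor of Janus kinases, reached its maximum at 1.45 h (interval 1.35 to 1.5 h). Ifit1 did so at 1.55 h (1.5 to 1.6 h), and Cxcl10 (1.55 to 1.75 h) and Usp18 (1.6 to 1.8 h) at 1.65 h. These intervals hold only the spread around a curve of fixed form. Without the 2 h array no array lies between 1.5 and 2.25 h. The highest single array was that of 1 h for Socs1 and Cxcl10, 1.25 h for Ifit1 and 2.25 h for Usp18. The order of these early maxima is therefore not resolved. The maxima of Irf7, Oasl2 and Ifitm3 were at 2.05 h (1.75 to 10.35 h), 2.75 h (2.25 to 6.20 h) and 3.00 h (2.6 to 3.25 h). The intervals of Irf7 and Oasl2 include that of Ifitm3, so the order of these later maxima is not resolved. With all arrays the intervals were 2.7 to 15 h for Oasl2 and 2.85 to 15 h for Ifitm3. No test between genes was made.

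Between 0.15-0.75 h and 1-1.5 h, 14 genes rose and 2 fell. Ifi207, of the interferon-inducible p200 family, was higher by 2.89 ± 0.52 (log2 difference ± SE, as in all that follow; 9.82 ± 0.21 against 6.94 ± 0.94, SD, n = 3 in each; adjusted p = 0.017). Zeb2, a transcriptional repressor, rose by 1.45 ± 0.27 (9.78 ± 0.23 against 8.33 ± 0.34; adjusted p = 0.019), and the nucleotide receptor genes P2ry14 and P2ry13 rose by 1.21 and 1.17. BC023105 rose by 2.26, Max, the partner of Myc, by 1.09 and the death receptor gene Fas by 0.81 ± 0.14 (adjusted p = 0.017). Cpm, a membrane carboxypeptidase, fell by 1.44 ± 0.28 (adjusted p = 0.032) and the kinase gene Stk17b fell by 0.68. The calls of Max (1.10) and Cpm (-1.44) ended with wording as a covariate (both adjusted p = 0.066). In all, 16 genes passed in limma, 14 higher and 2 lower, and 10 of them were at least 2-fold different. Quantile normalisation gave 55 higher and 22 lower. The balance was nearer to even without the 5 compressed arrays, with 430 higher and 375 lower, and with array weights, with 305 and 274.

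The best-known interferon-induced genes had large differences in this contrast that did not pass with all arrays. Cxcl10 was 3.57 ± 0.76 higher (12.11 ± 0.26 against 8.54 ± 1.74; adjusted p = 0.058), Ifitm3 3.35 (adjusted p = 0.21), Usp18 2.40 (adjusted p = 0.45), Ifit1 1.82 (adjusted p = 0.70), Irf7 1.74 (adjusted p = 0.65) and Mx1 1.73 (adjusted p = 0.74). The reference window itself held arrays from 8.65 to 11.96 for Ifit1. Without the 2 h array, which is in neither window but adds to the shared spread, Ifitm3 had an adjusted p of 8.6e-07, Cxcl10 of 0.00016, Socs1 (difference 1.93) of 0.0012, Usp18 of 0.014, Irf7 of 0.015 and Ifit1 of 0.023, and 228 genes passed, 203 of them higher, among them all 16. The differences of Mx1, Irf1 (0.48) and Cd69 (0.95) did not pass there either.

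Lists of interferon-response genes were higher as groups in 1-1.5 h. No member of the 27 antiviral effectors passed over all genes, 18 were higher when adjusted over the list alone, and the median difference was 1.61 (camera adjusted p = 1.41e-22; adjusted p = 0.101 with an estimated correlation). Examples are Rsad2, the source of a chain-terminating nucleotide, at 2.57, and Oas3, which makes the activator of RNase L, at 2.19. Of 16 nucleic acid sensors 10 were higher adjusted over the list alone (median 0.79; adjusted p = 7.45e-15, and 0.0445 with an estimated correlation), such as Ifih1 at 2.49 and Tlr3 at 1.76. Of 8 interferon-inducible GTPases 7 were (median 1.24; adjusted p = 1.12e-12, and 0.0493 with an estimated correlation), such as Gbp7 at 1.96 and Gbp4 at 1.56. Of 17 ubiquitin-like and PARP genes 8 were (median 0.99), such as Parp12 at 2.57, with an adjusted p of 0.102 with an estimated correlation. Of 20 interferon pathway transcription factors 8 were (median 0.53; adjusted p = 0.123 with an estimated correlation). Of 25 chemokines and cytokines 5 were (median 0.18; adjusted p = 0.0445 with an estimated correlation), such as Tnfsf10, a death ligand, at 2.28 and Il15 at 2.12. With the 2 h array left out, 17 antiviral effectors passed over all genes and the list kept its call with an estimated correlation (adjusted p = 0.00952).

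Lymphocyte trafficking genes were lower in 1-1.5 h (median -0.30; 5 of 20 adjusted over the list alone; adjusted p = 0.0445 with an estimated correlation), with S1pr1, the receptor that leads lymphocytes out of tissue, at -1.01. Sterol synthesis genes were lower (median -0.25, 3 of 19 adjusted over the list alone, adjusted p = 0.0972 with an estimated correlation), with Sc5d at -0.69, and so were the interferon receptor and kinases (median -0.24, 3 of 8, adjusted p = 0.338 with an estimated correlation), with Ifnar1 at -0.97. Fas was the 1 member that passed in the lists of cell death (median 0.22, 8 of 20 adjusted over the list alone, adjusted p = 0.0972 with an estimated correlation) and of B cell activation (median 0.06, 4 of 16, adjusted p = 0.296 with an estimated correlation). Casp4 was at 1.48, the costimulator gene Cd86 at 1.33 and Il2ra at 1.51. MHC class I presentation (median 0.27) and cell cycle (0.19) were called higher, with an adjusted p of 0.407 and 0.727 with an estimated correlation. Ribosomal proteins (-0.27), B cell identity (-0.16), glucocorticoid targets (-0.23), circadian clock (-0.15) and oxidative phosphorylation (-0.16) were called lower, with an adjusted p of 0.463, 0.463, 0.101, 0.0881 and 0.542 with an estimated correlation. The 16 calls by gene fell to 0 without any 1 of the arrays of 0.15, 0.5, 1 or 1.5 h. They numbered 10 without the 1.25 h array, 71 without 0.75 h, 33 without 2.25 h and 32 without 3.75 h. Without the 6 arrays out of order the reference is the 0.5 h array alone, so no count is given for that fit.

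By 2-2.75 h, with all arrays in the fit, 263 genes had fallen and 74 had risen, a balance that turned to 1189 higher and 611 lower without the 5 compressed arrays and to 1033 and 660 with array weights. Gimap3, a GTPase of lymphocyte survival, fell by 1.49 ± 0.21 (8.64 ± 0.50, n = 4, against 10.13 ± 0.04, n = 3; adjusted p = 0.0020), Cpm fell by 1.69 ± 0.26 (adjusted p = 0.0029), Antxr2, an anthrax toxin receptor, fell by 1.43 (adjusted p = 0.0043) and Pgap1 fell by 1.35 (adjusted p = 0.0029). P2ry14 rose by 1.35 (adjusted p = 0.0029), Parp12 by 2.43 ± 0.58 (adjusted p = 0.033), the transcript 9330175E14Rik by 2.39, Ifi207 by 2.15, Phf11d by 1.97, Rpp38, a subunit of RNase P, by 1.40 and Dctd, the dCMP deaminase, by 1.31. The calls of Gimap3, Cpm, Antxr2, Pgap1 and P2ry14 held whichever 1 array was left out. With wording as a covariate, in a window that is all wording A, those of Parp12 (2.62, adjusted p = 0.13), 9330175E14Rik (2.14, adjusted p = 0.14), Ifi207 (2.08, adjusted p = 0.14), Phf11d (2.15, adjusted p = 0.13), Rpp38 (1.05, adjusted p = 0.21), Dctd (1.08, adjusted p = 0.13) and Antxr2 (-1.30, adjusted p = 0.057) ended, with differences of similar size for all but Rpp38 and Dctd. In limma 337 genes passed in all, 55 of them at least 2-fold different, but 0 passed with only the 2 windows compared. The fit without the 6 arrays out of order has the 0.5 h array alone as its reference, so its count is left out. Quantile normalisation gave 254 higher and 355 lower and median centring 28 higher and 56 lower. The fit lacking the 2 h array gave 440 higher and 440 lower, with 315 of the 337 among them.

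The antiviral effectors in 2-2.75 h carried the imprint of the 2 h array. Ifitm3 was at 10.92 ± 3.28 (n = 4), 2.72 higher than in the reference (adjusted p = 0.12), and Ifit1 was at 10.45 ± 2.69, a difference of -0.06. Without the 2 h array Ifitm3 was higher by 4.36 ± 0.31 (adjusted p = 2.3e-09), Oasl2 by 2.75 (adjusted p = 8e-08) and Oas3 by 3.28, and Ifit1 differed by 1.27 (adjusted p = 0.089), or by 3.13 against the single 0.15 h array (adjusted p = 5.2e-07). Of the 27 antiviral effectors, 0 passed over all genes in limma, 3 adjusted over the list alone (median 0.51; camera adjusted p = 0.0019; adjusted p = 0.802 with an estimated correlation). Among them 16 rose once the 2 h array was left out (median 1.29). Nucleic acid sensors (median 0.39; 3 of 16 adjusted over the list alone) and ubiquitin-like and PARP genes (median 0.30; 1 rose, Parp12, and 3 of 17 adjusted over the list alone) were called higher, both with an adjusted p of 0.802 with an estimated correlation. Chemokines and cytokines were called too (median 0.20, 1 of 25 adjusted over the list alone; adjusted p = 0.583 with an estimated correlation). MHC class I presentation was not called with all arrays (median 0.20). Its members Psmb10, of the immunoproteasome, and Nlrc5, the class I transactivator, differed by 1.17 (adjusted p = 0.086) and 1.00 (adjusted p = 0.25), and by 1.55 (adjusted p = 0.0037) and 1.70 (adjusted p = 0.00012) without the 2 h array.

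Genes of the interferon receptor and kinase list, of B cell identity and of sterol synthesis were lower in 2-2.75 h. This window holds compressed arrays at 2 and 2.5 h. The first list includes Ifngr1 and Ifngr2 beside Ifnar1 and Ifnar2, and so is not the interferon alpha receptor alone. Of 8 interferon receptor and kinase genes Ifnar1 fell by 0.90 ± 0.20 (adjusted p = 0.026) and Ifngr1 fell by 0.66 (adjusted p = 0.037), 3 were lower adjusted over the list alone, and Jak2 was at -0.73 (median -0.44; adjusted p = 0.616 with an estimated correlation). Of 22 B cell identity genes 3 fell, Syk (-0.89), Ralgps2 (-0.79) and Btk (-0.71), and 6 were lower adjusted over the list alone (median -0.27; camera adjusted p = 1.44e-05; adjusted p = 0.616 with an estimated correlation). Syk and Btk are kinases of the B cell receptor. Of 19 sterol synthesis genes Cyp51 (-0.66) and Sc5d (-0.65) fell and 9 were lower adjusted over the list alone (median -0.35; camera adjusted p = 1.44e-05; adjusted p = 0.583 with an estimated correlation). Ccr6, a chemokine receptor of B cells, fell by 1.03, and glucocorticoid targets were called lower (median -0.15; 0 passed over all genes in limma and 2 of 15 adjusted over the list alone; adjusted p = 0.583 with an estimated correlation). Without the 5 compressed arrays the medians were -0.27 for receptor and kinases, -0.23 for B cell identity and -0.23 for sterol synthesis, the last and the first were no longer called (both adjusted p = 0.079), and neither were the calls of Cyp51 (-0.45) and Sc5d (-0.49). With wording as a covariate 24 genes were called, and of the genes named here only Sc5d (-0.84, adjusted p = 0.040) kept its call. The differences of the others there were Ifnar1 -0.86, Ifngr1 -0.57, Syk -0.70, Ralgps2 -0.65, Btk -0.67, Cyp51 -0.71 and Ccr6 -0.98. Leaving out 1 array gave 25 without the 2.5 h array, 42 without 0.15 h, 64 without 0.75 h, 95 without 0.5 h, 224 without 13 h, 528 without 3.75 h and 567 without 4.5 h.

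In 3-4 h the strongest antiviral genes stood clear of the reference with all arrays in the fit. Ifitm3 rose by 4.35 ± 0.89 (12.55 ± 0.10, n = 4, against 8.20 ± 1.04, n = 3; adjusted p = 0.0081), Oasl2 by 2.69 ± 0.57 (adjusted p = 0.0094) and Oas3 by 2.54 (adjusted p = 0.039), and these 3 were the members of the 27 antiviral effectors that passed over all genes (11 adjusted over the list alone; median 0.99; camera adjusted p = 1.83e-06; adjusted p = 0.699 with an estimated correlation). Parp12 (2.67), Ube2l6 (2.56), the conjugating enzyme of Isg15, and Herc6 (1.92), its ligase, rose among 17 ubiquitin-like and PARP genes (5 adjusted over the list alone; median 0.48; adjusted p = 0.711 with an estimated correlation). Ifih1 (2.21), Ddx60 (2.26) and Ifi205 (1.26) rose among 16 nucleic acid sensors (4 adjusted over the list alone; median 0.43; adjusted p = 0.699 with an estimated correlation). Il15 rose by 1.56 as the 1 member of 25 chemokines and cytokines (3 adjusted over the list alone; median 0.13; adjusted p = 0.588 with an estimated correlation), Il2ra by 1.13 and Mlkl, the executor of necroptosis, by 1.36. Irf7 was 1.70 higher (adjusted p = 0.24, and 0.0045 without the 2 h array). Ifit1 (0.49), Usp18 (1.41), Cxcl10 (1.37) and Mx1 (0.61) did not pass. The call of Ifi205 ended without the 5 compressed arrays (0.73, adjusted p = 0.10). None of the genes named here kept its call with wording as a covariate, though the differences of Ifitm3 (4.28, adjusted p = 0.058), Oasl2 (2.79, adjusted p = 0.055), Parp12 (2.86, adjusted p = 0.055), Herc6 (2.16, adjusted p = 0.077), Oas3 (2.99, adjusted p = 0.082), Ube2l6 (2.55, adjusted p = 0.088), Ifih1 (2.45, adjusted p = 0.098) and Ddx60 (2.37, adjusted p = 0.10) were about as large or larger.

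With all arrays 392 genes fell and 212 rose in 3-4 h, and without the 5 compressed arrays, of which it holds 2, 371 fell and 753 rose. Gimap3 fell by 1.99 ± 0.21 (8.15 ± 0.43 against 10.13 ± 0.04; adjusted p = 7.6e-06), Antxr2 fell by 1.82 and Pgap1 fell by 1.57 (both adjusted p = 0.00027), Clec12a, an inhibitory lectin, fell by 1.81 (adjusted p = 0.0056) and Tsc22d3, a glucocorticoid-induced gene, fell by 1.49 (adjusted p = 0.0090). Jak2 fell by 0.95 ± 0.19 (adjusted p = 0.0085), Ifngr1 fell by 0.77 and Ifnar1 fell by 0.79, which made 3 of the 8 interferon receptor and kinase genes (5 adjusted over the list alone; median -0.50; adjusted p = 0.435 with an estimated correlation). Stat4 fell by 0.90 and Trim24 fell by 0.72. Of the 22 B cell identity genes 6 fell, namely Fcer2a (-1.15), the low-affinity IgE receptor, Ebf1 (-0.97), a factor of B lineage commitment, Cr2 (-0.86), Syk (-0.84) and, named after their values were seen, Btk (-0.69) and Ralgps2 (-0.61). Adjusted over the list alone 10 were lower (median -0.36; camera adjusted p = 4.89e-08; adjusted p = 0.435 with an estimated correlation). Compressed arrays at 3.75 and 4 h made up part of this window, and without the 5 compressed arrays the B cell identity median was -0.07 (adjusted p = 0.048), that of receptor and kinases -0.17 (adjusted p = 0.074), and the calls of Ifnar1 (-0.48), Syk (-0.51), Ralgps2 (-0.45) and Itgb7 (-0.53) ended. Those of Gimap3 (-1.65), Jak2 (-0.82), Ebf1 (-0.65), Fcer2a (-0.76) and Cr2 (-0.71) held in that fit. With wording as a covariate Gimap3, Antxr2, Clec12a, Pgap1 and Stat4 kept their calls, while those of Jak2 (-0.89, adjusted p = 0.071), Ebf1 (-0.86, adjusted p = 0.094), Fcer2a (-1.10, adjusted p = 0.098), Cr2 (-0.78, adjusted p = 0.17), Tsc22d3 (-1.45, adjusted p = 0.068), Trim24 (-0.72, adjusted p = 0.066), Ifnar1 (-0.75), Ifngr1 (-0.68), Syk (-0.65), Btk (-0.65) and Ralgps2 (-0.47) ended.

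Smaller groups in 3-4 h moved both ways. Mcm6, a helicase subunit of S phase, rose by 1.01 ± 0.20 (adjusted p = 0.0068), and Ccne2, cyclin E2, chosen after its value was seen, rose by 0.90 (adjusted p = 0.030), the 2 members of 27 cell cycle genes that passed (5 adjusted over the list alone; median 0.33; adjusted p = 0.699 with an estimated correlation). With wording as a covariate that median was 0.11, the cell cycle list was not called (adjusted p = 0.10), and Mcm6 (0.99, adjusted p = 0.056), Ccne2 (0.50, adjusted p = 0.40), H2-Ob (-0.79, adjusted p = 0.13), Ccr6 (-0.93, adjusted p = 0.15) and Itgb7 (-0.76, adjusted p = 0.15) did not pass. Ccne2 did not pass without the 5 compressed arrays either (0.69, adjusted p = 0.17). H2-Ob, a class II chaperone chain, fell by 0.81 as the 1 member of 10 MHC class II genes (3 adjusted over the list alone; median -0.27; adjusted p = 0.685 with an estimated correlation). Ccr6 (-0.97) and Itgb7 (-0.91) fell among 20 lymphocyte trafficking genes (3 adjusted over the list alone; median -0.28; adjusted p = 0.399 with an estimated correlation). Sterol synthesis genes were called lower (0 passed over all genes in limma, 8 of 19 adjusted over the list alone; median -0.23; adjusted p = 0.435 with an estimated correlation), and so were ribosomal proteins (median -0.33, 3 of 21 adjusted over the list alone; adjusted p = 0.711 with an estimated correlation). Among 15 glucocorticoid targets Tsc22d3 fell and 5 were lower adjusted over the list alone (median -0.18; adjusted p = 0.588 with an estimated correlation). Without the 5 compressed arrays the medians were 0.00 for MHC class II presentation, 0.03 for ribosomal proteins, -0.21 for sterol synthesis and -0.23 for lymphocyte trafficking, and none of these 4 lists was called.

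In all, 604 genes passed in 3-4 h in limma, 134 of them at least 2-fold different. The calls of Gimap3, Antxr2, Clec12a, Pgap1, Jak2, Mcm6 and Stat4 held whichever 1 array was left out. With wording as a covariate 64 genes were called, 27 higher and 37 lower. Leaving out 1 array gave 155 without the 0.15 h array, 231 without 0.75 h, 272 without 4 h, 372 without 3.75 h, 384 without 0.5 h and 1080 without 3.5 h, and only the 2 windows compared gave 68. No count is given without the 6 arrays out of order, where the reference is the 0.5 h array alone.

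Few genes passed in 4.5-6.5 h. Pgap1 fell by 1.35 ± 0.20 (9.49 ± 0.25, n = 5, against 10.84 ± 0.04, n = 3; adjusted p = 0.0037), Bbs9 fell by 0.89 (adjusted p = 0.0037), Pde3b, a phosphodiesterase, fell by 1.45 (adjusted p = 0.0096), Gimap3 fell by 1.15 and Jak2 fell by 1.09 ± 0.19 (both adjusted p = 0.013). The transcript 9330175E14Rik rose by 2.48 ± 0.48 (adjusted p = 0.029), the cytokine gene Mif by 1.10 ± 0.20 (adjusted p = 0.014) and Ranbp1, a cofactor of nuclear transport, by 0.67 (adjusted p = 0.039). Ifitm3 was 3.53 higher (adjusted p = 0.13), Oasl2 2.40 (adjusted p = 0.089) and Irf7 1.98 (adjusted p = 0.47), with 2.3e-08, 2.1e-07 and 0.0036 without the 2 h array, while Ifit1 (-0.11), Cxcl10 (-0.27) and Socs1 (-0.08) did not pass. The reference holds arrays in which these genes were already high, and against the single 0.15 h array, without the 2 h array, Ifit1 was 1.74 higher (adjusted p = 0.0029). In limma 21 genes passed, 3 higher and 18 lower, and median centring gave 0 higher and 2 lower. The balance turned to 52 higher and 44 lower without the 2 h array, 181 and 113 without the 5 compressed arrays, and 32 and 25 within wording B (2 against 5 arrays), where Ifitm3 (3.52, adjusted p = 0.0011), Oasl2 (2.28) and Irf7 (1.76) passed. Every fit within wording B also leaves out the 2 h array and all compressed arrays but that of 4.5 h. It is thus not separate from the fits without those arrays. In the fit of both wordings the count was 96 without the 2 h array, 34 without 3.75 h, 11 without 5.5 h, 9 without 4.5 h, 4 without 0.5 h, 3 without 0.15 h and 0 without 0.75 h. The fit without the 6 arrays out of order, with the 0.5 h array alone as its reference, is left out.

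Antiviral genes as a group were still higher in 4.5-6.5 h. Of 27 antiviral effectors 0 passed over all genes in limma, 4 were higher adjusted over the list alone and the median was 0.75 (camera adjusted p = 1.13e-11; adjusted p = 0.638 with an estimated correlation), with Oas3 at 2.41. MHC class I presentation was called higher (4 of 18 adjusted over the list alone; median 0.27; adjusted p = 0.638 with an estimated correlation), with Nlrc5 at 1.16 and Psmb10 at 1.04. Ubiquitin-like and PARP genes (median 0.39, 3 of 17 adjusted over the list alone) and nucleic acid sensors (0.18) were called higher with an adjusted p of 0.805 with an estimated correlation, and cell cycle (0.15) and oxidative phosphorylation (0.10) with 0.867. Jak2 was the 1 of 8 receptor and kinase genes that fell (2 adjusted over the list alone; median -0.25; adjusted p = 0.638 with an estimated correlation). Glucocorticoid targets (-0.18; 1 of 15 adjusted over the list alone) and B cell identity (-0.12) were called lower, with an adjusted p of 0.228 and 0.867 with an estimated correlation. The window holds 1 compressed array, and without the 5 such arrays the medians of receptor and kinases and of B cell identity were -0.09 and -0.01 and neither was called.

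No gene passed in 7-10 h with all arrays (limma, 0 genes; 803 at an unadjusted p under 0.05). The antiviral genes that last longest were still far above the reference mean, Ifitm3 by 3.36 ± 0.89 (11.56 ± 0.18, n = 4, against 8.20 ± 1.04, n = 3), Oasl2 by 2.46, Oas3 by 2.44 and Irf7 by 2.10, and these 4 had adjusted p of 0.87, 0.54, 1.00 and 1.00. Without the 2 h array they had 1.9e-07, 3.5e-07, 0.0051 and 0.0051, and 17 genes were higher and 2 lower. Within wording B (2 against 4 arrays) 20 genes were higher and 1 lower, with Ifitm3 (3.36) and Oasl2 (2.34) at an adjusted p of 0.0032 and Oas3 and Irf7 at 0.012. Cd69, an early activation marker, was at -0.96 and Jak2 at -0.66. Camera called antiviral effectors (median 0.80, 4 of 27 adjusted over the list alone, adjusted p = 9.91e-12), MHC class I presentation (0.36, with Nlrc5 at 1.04 and Psmb10 at 1.02), cell cycle (0.31, with Mcm6 at 0.67 and Ccna2 at 0.78, or 1.27 with wording as a covariate), ubiquitin-like and PARP genes (0.41, 1 of 17 adjusted over the list alone), nucleic acid sensors (0.30) and sterol synthesis (0.16) higher, all with an adjusted p of 0.68 with an estimated correlation. Interferon pathway transcription factors (0.23), oxidative phosphorylation (0.12), marginal zone B cells (0.11) and immediate early genes (0.10) were called higher and myeloid markers (-0.13) lower, all with an adjusted p of 0.706 with an estimated correlation. Glucocorticoid targets were called lower (-0.19, 1 of 15 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation). Fry called 0 lists here.

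The last window, 11-15 h, had no gene past the threshold either (limma, 0 genes; 1423 at an unadjusted p under 0.05). Ifitm3 was 3.24 ± 0.85 above the reference (11.44 ± 0.40, n = 5, against 8.20 ± 1.04, n = 3; adjusted p = 0.25), Oasl2 2.21 (adjusted p = 0.22), Irf7 1.72 (adjusted p = 0.51) and Oas2 1.37 (adjusted p = 0.50). Without the 2 h array these had adjusted p of 1.5e-07, 1.3e-06, 0.041 and 0.045, Tnf (0.84) had 0.044, and 16 genes were higher and 1 lower. Within wording B (2 against 2 arrays) 6 genes were higher, among them Ifitm3 (3.30, adjusted p = 0.022) and Oasl2 (2.15, adjusted p = 0.037). The counts without 1 array were also 6 without the 0.15 h array, 4 without 12 h and 2 without 2.75 h. Ifit1 (-0.29), Socs1 (-0.36), Cxcl10 (0.46), Mx1 (-0.65) and Cd69 (-1.19) did not pass. For Ifit1 the direction turned with the reference, to 1.56 higher than the single 0.15 h array without the 2 h array (adjusted p = 0.022). Cell cycle genes were called higher (median 0.38; camera adjusted p = 1.3e-08; adjusted p = 0.843 with an estimated correlation). Their member Ccna2, cyclin A2, was at 1.24 (adjusted p = 0.48), and at 0.84 with wording as a covariate, and did not pass. Also called higher were MHC class I presentation (0.26, with Psmb10 at 1.04), antiviral effectors (0.37, 2 of 27 adjusted over the list alone), nucleic acid sensors (0.22) and immediate early genes (0.16). Glucocorticoid targets were called lower (-0.14), with 1 of 15 higher and 2 lower adjusted over the list alone. All 6 had an adjusted p of 0.843 with an estimated correlation, and fry called 0 lists.

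**Figure D2:**
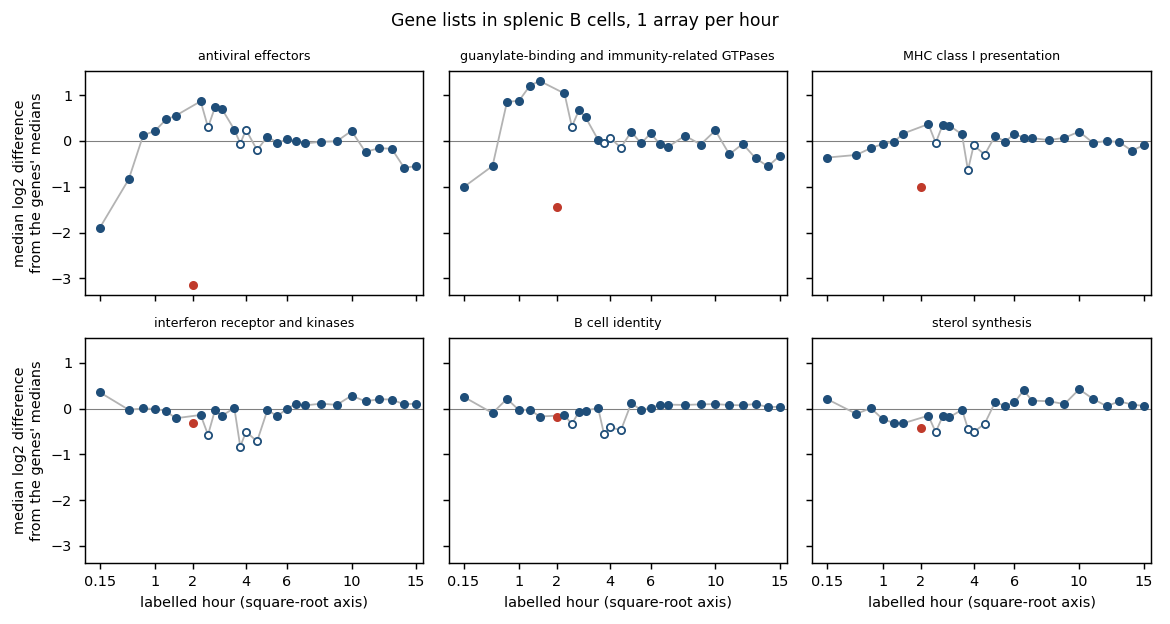
Median log2 difference of the members of gene lists from each gene's own median over the arrays (y axis) against the labelled hour (x axis, square-root scale), with 1 point per array, open points for compressed arrays, a red point for the 2 h array and a grey line that passes over it. The antiviral effectors run from -1.90 at 0.15 h to 0.87 at 2.25 h and -0.55 at 15 h, with -3.14 at 2 h.

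The comparison of 11-15 h with 2-2.75 h asked which genes had come back by the end. Ceacam1, an adhesion receptor, rose by 1.23 ± 0.25 (11.03 ± 0.24, n = 5, against 9.80 ± 0.72, n = 4; adjusted p = 0.0097), its relative Ceacam2 by 1.83 (adjusted p = 0.024), Cpm by 1.50 (adjusted p = 0.0022), Myadm by 1.45, Scd2, a fatty acid desaturase, by 1.31 and Smpd1, acid sphingomyelinase, by 1.24. Rundc3b fell by 1.35 ± 0.20 (adjusted p = 0.0022), Tktl1 fell by 1.23, P2ry14 fell by 1.01 and Rrs1, a ribosome assembly factor, fell by 0.94. The calls of Cpm, Myadm, Rundc3b, P2ry14 and Rrs1 held whichever 1 array was left out. In limma 506 genes passed, 437 higher and 69 lower, 37 of them at least 2-fold different, and 284 passed with wording as a covariate. Without the 6 arrays out of order 0 passed, but there 11-15 h keeps only 2 arrays, both of wording B. The 4 arrays of 2-2.75 h are all of wording A, so hour and wording cannot be told apart in that fit. Quantile normalisation gave 244 higher and 168 lower. The balance turned to 644 higher and 1010 lower without the 5 compressed arrays. Within wording A (4 against 3 arrays) 0 genes passed in limma, with Cpm at 1.52, Rundc3b at -1.41 (both adjusted p = 0.28) and Ceacam1 at 1.30 (adjusted p = 0.31). These differences were about as large as with all arrays. Wording A holds the compressed arrays of 2, 2.5, 3.75 and 4 h, which enter its spread. The count of 0 therefore cannot tell an effect of wording from that spread.

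Sterol synthesis genes stood out among the lists in this contrast. Of 19 members 4 rose, Cyp51 (0.67 ± 0.15; adjusted p = 0.016), Dhcr7 (0.69), Msmo1 (0.73; adjusted p = 0.049) and, named after its value was seen, Sc5d (0.62), and 16 were higher adjusted over the list alone (median 0.43; camera adjusted p = 3.13e-09; adjusted p = 0.478 with an estimated correlation; fry adjusted p = 0.00786). Srebf2, the master regulator of the pathway, was at 0.77 (adjusted p = 0.072). Among 8 receptor and kinase genes Ifngr2 (0.70) and Ifnar2 (0.59) rose (4 adjusted over the list alone; median 0.43; adjusted p = 0.844 with an estimated correlation), and Ifnar1 was at 0.60. Of 22 B cell identity genes 0 passed over all genes in limma and 8 were higher adjusted over the list alone (median 0.34; adjusted p = 0.844 with an estimated correlation), with Fcer2a at 0.67 and Syk at 0.59. Oxidative phosphorylation (0.22) and cell cycle (0.19) were called higher and the interferon-inducible GTPases lower (-0.46), each with an adjusted p of 0.844 with an estimated correlation. Chemokines and cytokines were called lower (-0.18, 2 of 25 adjusted over the list alone; adjusted p = 0.767 with an estimated correlation). The compressed arrays of 2 and 2.5 h are in the earlier window. Without the 5 compressed arrays the medians were 0.31 for sterol synthesis, 0.30 for receptor and kinases, 0.18 for B cell identity and 0.02 for oxidative phosphorylation, and Dhcr7 (0.40), Msmo1 (0.36), Sc5d (0.45) and Ifnar2 (0.41) no longer passed. Msmo1 (0.66, adjusted p = 0.12), Ifngr2 (0.68, adjusted p = 0.089) and Ifnar2 (0.57, adjusted p = 0.086) did not pass with wording as a covariate. Within wording A, whose fit keeps the 2 h array, none of these genes passed, with Cyp51 at 0.67, Dhcr7 at 0.65, Msmo1 at 0.67 and Sc5d at 0.70.

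The decline of the interferon-induced genes between the same windows was visible without the 2 h array. With all arrays Ifit1 differed by -0.23, Mx1 by -0.52, Cxcl10 by -1.38, Il15 by -1.16 and Ifitm3 by 0.52, and none passed. Without the 2 h array Cd69 fell by 1.67 (adjusted p = 0.00022), Il15 fell by 1.80 (adjusted p = 0.00013), Cxcl10 fell by 2.45 (adjusted p = 0.0015), Ifit3b fell by 2.12, Mx1 fell by 1.78, Tnfsf10 fell by 1.77, Gbp7 fell by 1.71, Ifit1 fell by 1.57 (adjusted p = 0.014), Socs1 fell by 1.23 and Ifitm3 fell by 1.12 (adjusted p = 0.018). There 16 of 27 antiviral effectors fell (median -1.12; adjusted p = 0.131 with an estimated correlation), and 892 genes passed. Other single arrays moved the count to 53 without 2.5 h, 179 without 13 h, 255 without 12 h, 269 without 14 h, 278 without 11 h, 326 without 15 h, 853 without 4.5 h, 890 without 3.75 h, 992 without 2.25 h and 1756 without 2.75 h.

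**Figure D3:**
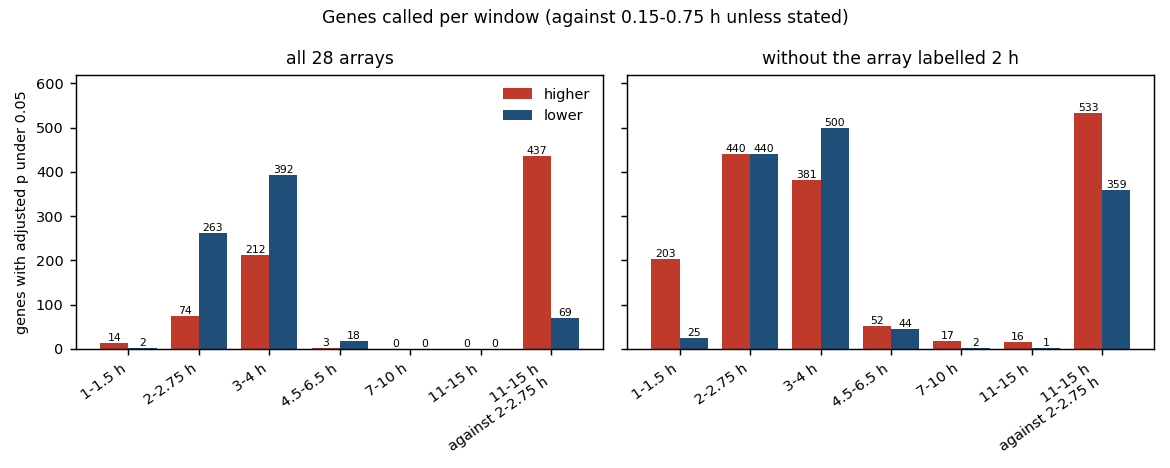
Number of genes called higher and lower (y axis) in each window contrast (x axis), with all 28 arrays and without the 2 h array. With all arrays 74 genes were higher and 263 lower in 2-2.75 h, and without the 2 h array 440 were higher and 440 lower.

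Of the list calls, only those in 1-1.5 h of nucleic acid sensors, GTPases, chemokines and cytokines, and lymphocyte trafficking held with an estimated correlation. Of 90 calls of genes followed by name, 17 held whichever 1 array was left out and 73 did not, most often without the 0.15, 0.5 or 0.75 h array of the reference. Values within a single preparation wording were compared because wording moved with the hour. Within wording A, from 2.25-3.5 h (5 arrays, including the compressed one of 2.5 h) to 11-15 h (3 arrays), all 27 antiviral effectors were lower (median -1.12), all 8 GTPases (-0.92) and 0 of 19 sterol synthesis genes (0.31), and B cell identity differed by 0.21. Ifit1 went from 11.48 ± 0.55 to 10.09 ± 0.13 and Usp18 from 12.06 ± 0.31 to 10.66 ± 0.37 (SD). Within wording B, from 0.75-1.25 h (2 arrays) to 4.5-10 h (9 arrays, including the compressed one of 4.5 h), 22 of 27 antiviral effectors were lower (median -0.24) and 7 of 8 GTPases (-1.10). Ifit1 differed by -1.78, Socs1 by -1.72 and Cxcl10 by -2.51, while Irf7 differed by 0.60 and Ifitm3 by 1.45. The 0.15 h array, also of wording B, was not in this early group. Within wording B, 4.5-6.5 h against 0.15-0.75 h gave 0.09 for Ifit1, -0.22 for Socs1 and -0.20 for Cxcl10. For these genes the size of the fall thus depends on which early arrays are taken.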

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

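The tests of the 2 h array and of the compressed arrays, with their bounds, were chosen after these patterns had been seen, while the prediction for the 6 arrays out of order was written before. Of 200 groups of 4 or 5 arrays tested for an array far from the others, 23 held one, 7 of them in the 2 h array. Chance flags about 1 in 20 groups of independent repeats. These groups span different hours and share arrays and genes, so the rate gives no expected number here.

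In the 2 h array, far below the other arrays of 2-2.75 h, were Irf7 at 7.00 (others 11.66 to 12.12), Usp18 at 6.91 (others 11.88 to 12.53), Ifit1 at 6.43 (others 11.60 to 12.15), Cxcl10 at 7.19 (others 11.31 to 11.72) and Ifitm3 at 6.00 (others 12.55 to 12.57). The medians of the antiviral effectors (7.65, others 11.08 to 11.57) and of MHC class I presentation (8.87, others 10.44 to 10.63) were low in it too. Chance flags about 1 in 20 groups of independent repeats, which these are not.

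In the 4.5 h array 6 list medians lay below those of the other arrays of 4.5-6.5 h. They were those of interferon pathway transcription factors (9.65; others 9.95 to 10.04), nucleic acid sensors (8.84; others 9.03 to 9.09), plasma cells (7.16; others 7.83 to 8.02), lymphocyte trafficking (8.25; others 9.01 to 9.29), cell death (7.65; others 7.95 to 8.06) and NF-kB targets (8.95; others 9.52 to 9.56). In the 3.75 h array negative feedback (8.28; others 9.16 to 9.30), cell death (7.74; others 8.20 to 8.28) and ribosomal proteins (10.18; others 11.21 to 11.42) lay below the other arrays of 3-4 h. Both arrays are among the 5 compressed ones. Chance flags about 1 in 20 groups of independent repeats, which these are not.

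Other single arrays stood apart in 1 or 2 values each. MHC class I presentation was low at 14 h (10.28; others 10.61 to 10.73) and sterol synthesis high at 13 h (7.80; others 7.58 to 7.62). MHC class II presentation was high at 2.25 h (12.15; others 12.01 to 12.03) and oxidative phosphorylation at 2.75 h (9.36; others 8.98 to 9.04). Lymphocyte trafficking (8.97; others 9.28 to 9.30) and immediate early genes (7.82; others 8.04 to 8.09) were low at 8 h. The upper quartile of intensity was high at 10 h (329, others 296 to 298). Chance flags about 1 in 20 groups of independent repeats, which these are not.

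For the 2 h array, compression does not account for the low antiviral effectors, whose median difference of -3.94 from the 1.5 and 2.25 h arrays lay beyond the lowest of 10000 lists matched on level (-1.24) by -2.70. A swap with another hour of the course does not either, since 25 of the 27 effectors had their lowest value of all arrays in it, below even 0.15 h. Other cells in place of B cells do not, since the 22 B cell identity genes differed by a median of -0.082. A sample from a mouse that did not respond, or from outside the series, may account for it and was not tested. No biological explanation was tested, since the design gives this array no group of its own.

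For the compressed arrays of 2 and 2.5 h, a change with the hour does not account for the compression. The 4 uncompressed arrays of 2.25, 2.75, 3 and 3.5 h had a median upper quartile of 300.8. That lies within the 258 to 329 of the 19 arrays outside 2-4.5 h and above the 227 to 255 of the 5 compressed ones. The compressed arrays of 3.75, 4 and 4.5 h follow each other with no uncompressed array among them. For these the test cannot decide whether the hour played a part. Other cells were weighed by the shift of 71 markers of T, NK, myeloid, dendritic and erythroid cells, 0.30, beside a median of 0.258 for lists matched on level, so dim genes of any kind shifted by nearly as much. This test replaced an earlier one that asked for a shift above an upper limit of the matched lists (0.307) and was undecided, with the markers at percentile 94.2. A small share of other cells therefore may remain, with NK markers at 0.39. RNA quality and hybridisation were not measured, stay open, and no biological explanation was tested.

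For the 6 arrays out of the order of hours, a swap of the early with the late ones was predicted to leave each nearer to the other end in its antiviral effectors. That held for 1 of 6, the 0.15 h array (distance 2.13 to the early end and 2.01 to the late end), so a swap does not account for their numbering. The 0.15 h array has the lowest Ifit1 after the 2 h array. Its hour remains the submitters' label, and no biological explanation was tested.

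Other splits of the arrays of the windows show how often a split calls as many genes as the real one, which each count includes. The share was under 0.05 for 4.5-6.5 h (1 of 56 splits reached the real 21 genes, highest other 2). It was also under 0.05 for 11-15 h against 2-2.75 h (2 of 100 drawn from 126 reached 506, highest other 1447). The same held for time dependence (4 of 100 orders of the hours reached 2036, highest other 9178). The share was not under 0.05 for 2-2.75 h (7 of 35 reached 337, highest other 5495) or 3-4 h (3 of 35 reached 604, highest other 2469). Splits and orders ignored wording and compression, and the shares were not adjusted over the tests. They therefore exclude neither chance nor a structure of the samples. For 7-10 h and 11-15 h the real count is 0, which all splits reach (35 of 35 and 56 of 56), so the splits tested nothing there. In 1-1.5 h, with 1 of 10 splits at the real 16, the splits are too few for a share under 0.05. The splits with 5495 and 2469 genes each set 0.15 and 0.75 h with 2 uncompressed later arrays, apart from the compressed ones, which points to a structure of the samples.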

How the results depend on the processing

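The fits without the 2 h array, without the 5 compressed arrays, with 0.15 h as the reference and within 1 wording were chosen after the results had been seen. Counts of genes moved with most choices, and the cause was not tested. All values below are genes called in 1-1.5, 2-2.75, 3-4, 4.5-6.5, 7-10 and 11-15 h against 0.15-0.75 h, then 11-15 h against 2-2.75 h, unless named otherwise, and the counts with all arrays were 16, 337, 604, 21, 0, 0 and 506. No paired analysis was possible because the replicate numbers come from the order of the records only. Background was not measured, so signal over background limits dim genes to an unknown degree.

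At 2-fold or more the counts were 10, 55, 134, 8 and, for the last, 37. The fit without the 6 arrays out of order leaves the 0.5 h array alone as the reference, so its counts against that reference are left out. It gave 0 genes and 11 lists in the last contrast, where 11-15 h keeps only the 12 and 13 h arrays. It gave 539 genes for time dependence. Quantile normalisation gave 77, 609 and 1235 in the first 3 and 8 in 11-15 h, and median centring 10, 84, 317 and 2. Array weights, whose fit gave a warning of convergence, gave 579, 1693, 4327, 667, 853, 1716 and 1751, with 3986 for time dependence. A reference of 0.15-1 h gave 0 in 1-1.5 h, 158 in 2-2.75 h and 35 in 4.5-6.5 h. Wording as a covariate gave 24 in 2-2.75 h, 64 in 3-4 h, 284 in the last and 1351 for time dependence, with 13 lists in 2-2.75 h and 10 in 11-15 h. Within wording B the counts were 57 in 4.5-6.5 h, 21 in 7-10 h and 6 in 11-15 h. Within wording A, which keeps the 2 h array, the count was 0 in the last. Only the 2 windows compared gave 0 in 2-2.75 h, 68 in 3-4 h, 34 in 7-10 h, 67 in 11-15 h and 312 in the last. All probe sets gave 3 in 7-10 h and 8 in 11-15 h, the brighter part of probe sets 2 and a variance trend 1 in 11-15 h, and 6 degrees of freedom 1322 for time dependence. Camera with an estimated correlation called 4, 0, 0, 0, 0, 0 and 0 lists and fry 4, 0, 0, 0, 0, 0 and 1, of 18, 8, 12, 9, 12, 6 and 7.

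Without the 2 h array the counts were 228, 880, 881, 96, 19, 17 and 892, with 15 lists in 2-2.75 h and 12 in the last. Without the 5 compressed arrays they were 805, 1800, 1124, 294, 168, 483 and 1654, with 15 and 16 lists. With 0.15 h alone as the reference, a single array whose own spread is unknown so that the error comes from the other windows, they were 0 in 2-2.75 h, 3 in 3-4 h and 0 in 4.5-6.5 h, with 14 lists in 4.5-6.5 h and 14 in 11-15 h. With 0.15 h alone and no 2 h array they were 203 in 1-1.5 h, 247 in 3-4 h, 51, 36 and 17, with 14, 16 and 15 lists in 2-2.75, 4.5-6.5 and 11-15 h. On that single reference array Ifit1 turned to 3.13 in 2-2.75 h, 1.74 in 4.5-6.5 h, 1.78 in 7-10 h and 1.56 in 11-15 h, and Mx1 to 2.91 and Cd69 to 1.40 in 2-2.75 h. Ifitm3 in 11-15 h against 2-2.75 h, which ranged from -1.12 to 1.07 with 1 array left out, turned to -1.12 without the 2 h array and to -1.12 without the compressed ones.

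Leaving out 1 array gave 0 to 228, 25 to 880, 155 to 1080, 0 to 96, 0 to 19, 0 to 17 and 53 to 1756 genes, and 1464 to 2602 for time dependence. The highest values in the first 2 contrasts and in 4.5-6.5, 7-10 and 11-15 h came without the 2 h array, that in 3-4 h without 3.5 h and the last without 2.75 h. The lowest in 2-2.75 h and in the last came without 2.5 h, and in 3-4 h without 0.15 h. Of 90 named calls 17 held without any 1 array. The median fitted maximum of the 59 induced genes ranged from 2.85 to 3.25 h and the half-rise from 0.70 to 1.50 h under the planned changes of the fit. That range leaves out the fit without the 2 h array, where 206 genes met the rule with medians of 2.175 and 0.6 h.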

Other observations

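The ribosome biogenesis test was chosen after late-rising genes had been seen in the course, with its prediction written before the list's own values were read. Ribosome biogenesis genes, which build ribosomal subunits in the nucleolus, were higher after the antiviral genes had risen. All 40 measured members of 42 were higher in 2.25-3.5 h (4 uncompressed arrays) than in 1-1.5 h (3 arrays), with a median difference of 0.74. That was above the highest of 10000 lists matched on level (0.323, percentile 100, median of matched lists 0.14). The matched lists were random genes, while the 40 may move together, and the percentile holds no spread between arrays. It is therefore no measure of significance. Polr1b, a subunit of RNA polymerase I, differed by 1.17 (8.48 ± 0.16 to 9.64 ± 0.18, SD), Rcl1 by 1.15, Rrp9 by 1.14, Tsr1 by 1.08, Gnl3 by 1.04 and Nop2 by 1.02. From 0.15-0.75 h the median differences were -0.10, 0.67, 0.36, 0.32 and 0.06 in 1-1.5, 2.25-3.5, 5-6.5, 7-10 and 11-15 h, beside 1.61, 1.29, 0.80, 0.80 and 0.37 for antiviral effectors. The order is consistent with a later wave of ribosome biogenesis, a hypothesis that came from these data. Within wording A alone the median was 0.76 (2 and 4 arrays) and all 40 were higher, and the limit to uncompressed arrays was set after compression had been seen.

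Of the 30 lists, 8 were called in none of the 7 contrasts with all arrays. Medians ranged from -0.12 to 0.04 for negative feedback (lowest camera adjusted p = 0.0792), -0.02 to 0.21 for plasma cells (0.126), -0.16 to 0.23 for heat shock (0.0643), -0.21 to 0.27 for NF-kB targets (0.066), -0.11 to 0.11 for T cell markers (0.0643), -0.12 to 0.22 for NK cell markers (0.0798), -0.08 to 0.18 for dendritic cell markers (0.131) and -0.18 to 0.13 for erythroid markers (0.105). Single members passed, some of them named after their values were seen. Of the 15 negative feedback genes, Socs1 and Usp18 did not pass in 1-1.5 h with all arrays. Without the 2 h array both did in limma (1.93, adjusted p = 0.0012, and 2.40, adjusted p = 0.014). A list without a call can thus hold induced members. Trim24, a brake on interferon signalling, fell by 0.72 in 2-2.75 h. In 11-15 h against 2-2.75 h Ptpn6, a phosphatase, rose by 0.50 and Creb3l2, a factor of secretory cells, by 0.59. Prkcq, a kinase of T cells, rose by 0.92 in 2-2.75 h and fell by 0.94 in 11-15 h against 2-2.75 h. With wording as a covariate Trim24 in 2-2.75 h (-0.72, adjusted p = 0.11), Ptpn6 (0.44, adjusted p = 0.097) and Prkcq in 2-2.75 h (0.88, adjusted p = 0.23) did not pass.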
